A study of Drosophila melanogaster with 11 samples.

How the data were processed

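Gene expression was measured by RNA sequencing in whole Drosophila melanogaster larvae of 2 genotypes at the early L3 larval stage, about 68 h after egg laying per the labels. Each library was made from the pooled RNA of 8 larvae, with 3 µg of RNA per sample and a TruSeq RNA version 2 kit, per the labels' protocols. The control strain w1118 had 6 libraries and the Activin-β mutant had 5. The mutants carried 2 different alleles of Actbeta: Actβ80, a chemically induced point change that creates an early stop codon, and Actβ4E, made with CRISPR/Cas9. The labels call the libraries biological replicates.

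The deposited table holds 1 whole-number read count per gene and library, which the authors made with Trimmomatic 0.33, HISAT2 2.1.0 and featureCounts, per the submitters' processing notes. The genome build was BDGP6, per the same notes. The strand setting of the counting and the annotation release are not given in the sources used here, so reads from overlapping or antisense genes cannot be told apart. The handling of reads that match several near-identical genes is not given either, so such genes are reported as uncertain. The table also holds the authors' signed fold change and FDR-corrected p-value from a comparison named an EDGE test with tagwise dispersions, per the file headers. These deposited values were only set beside the calls made here. A second comparison in the authors' table, against a genotype with no library here, was not used here.

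The counts were analysed as deposited, with no row that names no gene. The table had 17807 genes, of which 15037 had at least 1 count and 10543 passed the expression filter of edgeR (filterByExpr with its default settings). Library totals were 23149099 to 30049635 counts, so 1 count stood for 0.0311 to 0.0437 CPM. Intervals and the floor of 3 counts for a group at 0 cover counting error only. Libraries were scaled with TMM factors, and CPM values use these factors. The main test was edgeR's quasi-likelihood test (glmQLFit with robust estimation, version 4.0.16 in R 4.3.3), with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. A gene past this threshold is called changed. Standard errors of log2 fold changes came from the same fit. All 11 libraries entered with genotype as the term. No 2 libraries agreed within sampling noise, and none was merged.

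Before the data were examined, 39 gene lists were fixed, covering metabolism, hormones, secreted larval proteins, cuticle, stress, translation and markers of the tissues of a whole larva. Of their 1086 members, 1077 were matched by symbol. Each list with at least 3 tested genes was tested with camera in limma 3.58.1 with the preset correlation of 0.01, and again with an estimated correlation and with fry. The p-values of the 39 lists were adjusted together. After the data were seen, 13 members in 7 lists were found whose known products are not what the list names, some because their symbols share a prefix. The lists were kept as fixed, and were tested again without these members: Cpr, RpLP0-like, RpL24-like, Mat1, Rrp1, bel, Myc, Oatp74D, Cyp18a1, Fbp1, Fbp2, dor and trc. Chromosome arms were compared with Fisher's exact test, 2-sided. Values of whole libraries, such as the share of counts from mitochondrial genes, were compared with a 2-sided exact permutation test over the 462 splits of the libraries. Gene coordinates come from an Ensembl annotation of the Release 6 assembly (BDGP6.54), matched on gene identifier. Identifiers were found for 99.46% of the genes.

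The named genes were chosen by a rule fixed before the data were examined. It takes Actbeta, and the 6 largest increases and the 6 largest decreases among called genes whose groups did not overlap and whose mean was at least 2 CPM. It takes the 2 called members with the smallest adjusted p of each list with 3 or more called members, and the 1 called member with the smallest adjusted p of other lists. It adds roX1, roX2, w and y as checks of the libraries, and Actbeta, daw, myo, babo, put and Smox as the Activin branch whatever their result. Other genes in the text serve as examples and were chosen after their values were seen.

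The procedure was tested on simulated counts for 10444 tested genes in which 200 genes were changed. The edgeR test recovered 76.1% of genes changed 1.5-fold, 85.1% of those changed 2-fold and 97.0% of those changed 4-fold. Among its calls 4.44% were unchanged genes, against 4.42% with limma-voom and 13.3% with DESeq2. In the real data far more genes were called (2740 of 10543). Their median absolute log2 fold change of 0.3953 is below a 1.5-fold change, the smallest simulated. These rates therefore need not hold for the real calls. With 10 simulated lists raised and 10 left alone, camera called all 10 raised lists and 0 of the others, but the simulated genes varied independently, which real genes do not.

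The alternatives were RLE and upper-quartile scaling, DESeq2 1.42.0, limma-voom, other filters on low counts, a test against a fold of 1.5, non-robust estimation, leaving out the 20 most abundant genes, leaving out each library, the replicate number as a block, and the 2 list tests above. Upper-quartile scaling, leaving out w1118 libraries 1 and 6 together, the level of roX1 as a covariate, the fit to the 10 libraries of the block without the block, and the lists without the 13 members were added after seeing the data. A planned change of pseudocount was not run, since the values are counts.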

Results

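Whole larvae of the control strain w1118 (6 libraries) and of a mutant of Activin-β (5 libraries) were compared at the early L3 larval stage. Activin-β is a secreted ligand of the TGF-β family, encoded by Actbeta, and the comparison asks which transcripts differ in larvae with 2 mutant alleles of this gene. Values are mean CPM (counts scaled to a common library size) ± SD over these 6 and 5 libraries, and log2 fold changes are mutant over w1118 ± SE, with adjusted p-values from edgeR's quasi-likelihood test. The libraries held 23149099 to 30049635 counts each, and the totals did not differ detectably between genotypes (exact permutation test, p = 0.697).

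The transcript of the mutated gene itself was not called. Actbeta (FBgn0024913, chromosome 4, 1077331 to 1084796 in BDGP6) stood at 2.14 ± 0.113 CPM in w1118 and 1.90 ± 0.342 CPM in the mutants (log2 fold change -0.17 ± 0.13, adjusted p = 0.39). A gene-level count does not read the sequence of either allele, so this level does not check the genotype. Of the other Activin ligands, daw rose from 18.8 ± 1.63 to 33.7 ± 2.66 CPM (0.84 ± 0.07, adjusted p = 5.4e-06). The ligand gene myo differed by -0.14 ± 0.05 (adjusted p = 0.047), a call lost in 9 of the 11 fits that leave out 1 library and with DESeq2 (adjusted p = 0.057). The receptor genes babo (0.00 ± 0.04, adjusted p = 0.99) and put (-0.01 ± 0.04, adjusted p = 0.87) and the signal transducer Smox (-0.08 ± 0.04, adjusted p = 0.11) were not called. In the list of TGF-β ligands, receptors and effectors, 2 of 23 tested genes rose and 2 fell, with 1 change when adjusted over the list alone, and the list was not called (adjusted p = 0.92).

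Across the genome 2740 of 10543 tested genes were called, 1273 higher and 1467 lower in the mutants. With upper-quartile scaling, added after seeing the data, 2786 were called, 1593 higher and 1193 lower. More genes were also higher than lower without w1118 library 1 (1334 and 1286) and with the stricter filter (1267 and 1231). RLE scaling (1367 and 1382) and limma-voom (1308 and 1411) kept more lower genes, so the balance of directions rests on the processing. At least 2-fold changes were seen for 383 genes, 185 higher and 198 lower, and the median absolute log2 fold change of called genes was 0.3953. In 1752 of the called genes all mutant libraries lay on the same side of all w1118 libraries, and such separation was seen in 17.07% of all tested genes, against a chance share of 0.4329%. When tested against a fold of 1.5, 261 genes were called, 169 higher and 92 lower. The authors' deposited table had 1854 genes at an FDR under 0.05, of which 1710 were tested here and 1637 were called here too, all in the same direction. The other 1103 genes called here, 40.3% of the 2740, were not under 0.05 in that table, among them SdhB (0.11 there), kdn (0.2), ATPsynD (0.23), S6k (0.23), cac (0.17), br (0.084), usp (0.19), tok (0.083), RpL10Ab (0.42) and myo (0.64).

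Several genes were listed in 1 genotype and nearly absent in the other. The eye pigment transporter gene w (X, 2790599 to 2796466), whose mutant allele gives the control strain its name, had 2 counts in total in w1118 and 1352 in the mutants, a ratio of CPM of 873 with a 95% counting interval of 241 to 7220. The lectin gene lectin-24A (2L, 3716800 to 3717773) had 0 counts in w1118 and 831 in the mutants, at least 358-fold higher against a floor of 3 counts over the group, while its 95% counting interval starts at 290. LysD, a lysozyme gene (3L, 1210717 to 1211196), rose from 1.84 ± 0.5 to 299 ± 20.4 CPM (7.35 ± 0.14, adjusted p = 4e-11). The adjacent LysC (3L, 1210485 to 1210726), annotated as a pseudogene, stood at 0.0654 ± 0.0802 and 110 ± 16.6 CPM (10.60 ± 0.58). These lysozyme genes are near-identical copies, and LysC overlaps LysD, so their separate values are uncertain. The noncoding RNA gene lncRNA:CR44459 (6.79 ± 0.46) and the protein-coding CG34278 (6.30 ± 0.36) completed the 6 largest increases. The body pigment gene y fell, from 15.8 ± 6.55 to 4.92 ± 2.04 CPM (-1.68 ± 0.35, adjusted p = 0.0057).

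Larval storage protein transcripts and the 4 tested salivary glue transcripts were higher in the mutants. In the list of storage proteins, the amino acid reserves that the fat body secretes, 5 of 6 tested genes rose and 1 fell, with the same numbers when adjusted over the list alone. The 4 genes of the storage proteins themselves all rose, and the other 2 are Fbp1, for their receptor, and Fbp2 (2.43, adjusted p = 0.018), for a fat body protein of the alcohol dehydrogenase family. Lsp1beta rose from 13200 ± 2320 to 26600 ± 1940 CPM (1.02 ± 0.11, adjusted p = 5.2e-05), Lsp1gamma by 0.89 ± 0.11 and Lsp2 from 165 ± 44.1 to 1970 ± 1150 CPM (3.57 ± 0.39, adjusted p = 0.00019), while Fbp1 changed by -1.85 ± 0.56 (adjusted p = 0.026). All 4 tested glue protein genes rose, all 4 also when adjusted over the list alone, among them ng2 (2.42 ± 0.23) and ng1 (1.92 ± 0.21), a pair of similar neighbouring genes on the X. The other 8 of the 12 glue genes in the list did not pass the expression filter. Sgs7, 1 of the 4, was under 1 CPM in both groups (0.275 ± 0.125 in w1118 and 0.741 ± 0.194 in the mutants). Of 9 salivary gland markers 6 rose and 0 fell, also when adjusted over the list alone, led by the prolyl hydroxylase genes PH4alphaSG2 (5.98 ± 0.37, from 0.167 ± 0.123 to 10.6 ± 1.14 CPM) and PH4alphaSG1 (1.28 ± 0.11), and this list shares ng1, ng2 and Sgs7 with the glue list. The 3 salivary gland markers not called were eyg (0.33 ± 0.24, adjusted p = 0.34), fkh (0.07 ± 0.08, adjusted p = 0.62) and Cad74A (-0.03 ± 0.10, adjusted p = 0.88). The storage list (camera, adjusted p = 3.2e-05), the glue list (2.2e-07) and the salivary gland list (1.9e-12) were called. With an estimated correlation the glue list (adjusted p = 0.039) and the salivary gland list (adjusted p = 0.0011) were still called, and the storage list was not (adjusted p = 0.22, and 0.081 with its 4 storage protein genes alone). The storage list was also not called by camera once the 20 most abundant genes were left out (adjusted p = 0.14), but these include storage protein genes of the list itself. Its median log2 fold change was then 2.45, against 1.21 with all genes, but over fewer members. That median lies at the level of Fbp2 (2.43), which is not a storage protein gene. It therefore cannot show whether the change of the storage protein genes holds. The 20 most abundant genes, which include storage proteins, took 19.1 ± 0.924% of counts in w1118 and 20.9 ± 0.564% in the mutants (exact permutation test, p = 0.0108, 0.0324 adjusted over 6 library measures).

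**Figure D1:**
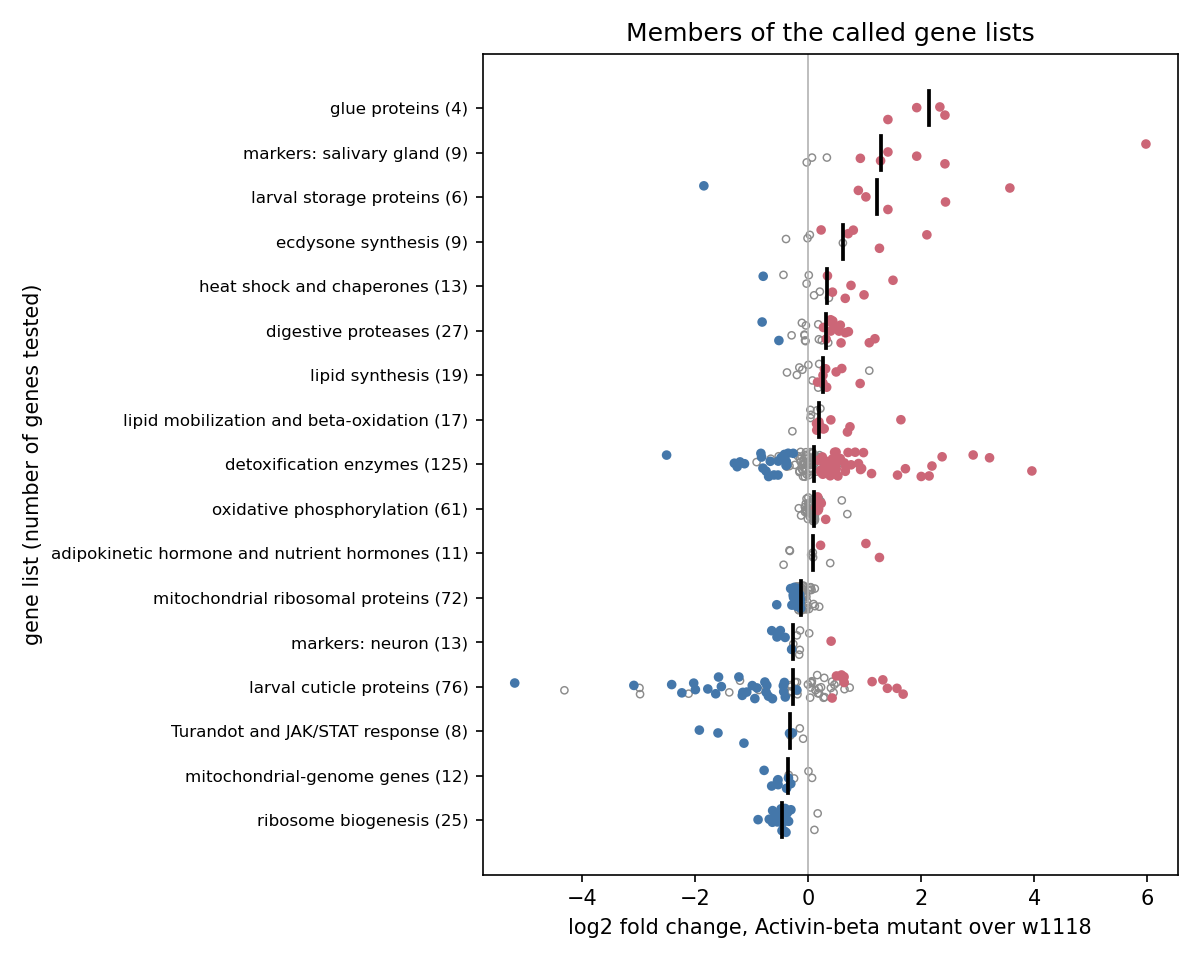
Each point is 1 tested gene of a called list, placed by its log2 fold change, mutant (n = 5) over w1118 (n = 6). Filled points are called genes, red where higher and blue where lower, open points are not called, and black bars are list medians, which run from -0.47 for ribosome biogenesis to 2.13 for glue proteins.

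In part, genes of fat breakdown and fat synthesis rose in the mutants. In the list of lipid mobilization and β-oxidation 10 of 17 genes rose and 0 fell (12 rose when adjusted over the list alone). Lip3, a lipase gene, rose from 19.2 ± 4.80 to 59.7 ± 11.6 CPM (1.64 ± 0.18, adjusted p = 7.5e-05), and Acox57D-p, a peroxisomal acyl-CoA oxidase gene, by 0.69 ± 0.07. The list was called (adjusted p = 0.00015), and also with an estimated correlation (adjusted p = 0.039). In lipid synthesis 9 of 19 rose and 0 fell (10 rose when adjusted over the list alone), among them the lipid droplet gene Lsd-1 (0.59 ± 0.09) and the desaturase gene Desat1 (0.33 ± 0.06). That list was called (adjusted p = 0.0074), but not with an estimated correlation (adjusted p = 0.66).

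Hormone genes tied to nutrition and to molting moved in part. Of 11 genes for adipokinetic and nutrient hormones 3 rose and 0 fell, also when adjusted over the list alone. They were the nutrient-responsive peptide gene CCHa2 (21.0 ± 1.71 to 42.7 ± 3.93 CPM, 1.02 ± 0.07, adjusted p = 1.5e-06), the adipokinetic hormone receptor gene AkhR (1.26 ± 0.12) and Gbp2. Of 9 genes of the ecdysone synthesis list 5 rose and 0 fell (6 rose when adjusted over the list alone), among them sro (2.1 ± 0.33) and nvd (1.26 ± 0.35, a call lost without mutant library 5), both near 1 CPM. One of the 5, Oatp74D (0.23 ± 0.07), encodes the importer of ecdysone, and Cyp18a1 (-0.39 ± 0.33, not called) an enzyme that degrades it, so that 4 of 7 synthesis genes rose (5 when adjusted over the list alone). These 2 lists were called (adjusted p = 0.025 and 0.039), and not with an estimated correlation (adjusted p = 0.31 and 0.66). The first call was lost without mutant library 1, 3 or 4 or w1118 library 3 (adjusted p up to 0.072) and with the replicate block (0.059), and the second without mutant library 1, 3, 4 or 5 or w1118 library 2 or 3 (up to 0.11). The ecdysone synthesis call was also lost with the stricter filter (adjusted p = 0.41) and without w1118 libraries 1 and 6 (0.054), but not without Oatp74D and Cyp18a1 (0.029, and 0.6 with an estimated correlation). The list of trehalose and sugar homeostasis was not called by camera (adjusted p = 0.15) but was by fry (adjusted p = 0.0072), with 4 of 14 genes higher and 1 lower, also when adjusted over the list alone. In it the sugar-responsive transcription factor gene sug (1.11 ± 0.13) and Pepck2 (1.15 ± 0.14), for a gluconeogenic enzyme, rose.

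Digestive, detoxifying and stress genes rose in larger part than they fell. Of 27 digestive protease genes 14 rose and 2 fell (16 and 2 when adjusted over the list alone). Jon99Ciii (1.18 ± 0.11) and Jon99Cii (1.08 ± 0.11), near-identical neighbours whose reads may be shared, had the smallest adjusted p, while alphaTry (-0.82 ± 0.17) and betaTry (-0.52 ± 0.13) fell. Of 125 detoxification genes 44 rose and 22 fell (45 and 24 when adjusted over the list alone), among them the cytochrome P450 gene Cyp28d2 (16.7 ± 3.19 to 126 ± 14 CPM, 2.92 ± 0.12) and the glutathione transferase gene GstZ1 (0.98 ± 0.05). Of 13 heat shock and chaperone genes 6 rose and 1 fell (7 and 1 when adjusted over the list alone), with Hsp68 up from 52.2 ± 12.5 to 148 ± 24.2 CPM (1.5 ± 0.16), DnaJ-1 up by 0.99 ± 0.10 and Hsp23 changed by -0.80 ± 0.18. The 3 lists were called (adjusted p = 1e-04, 0.0042 and 0.00076), and none of them with an estimated correlation (adjusted p = 0.66, 0.75 and 0.19).

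Transcripts for building ribosomes were lower in the mutants. Of 25 genes of the ribosome biogenesis list 23 fell and 0 rose (23 and 1 when adjusted over the list alone), with a median log2 fold change of -0.47. The 2 others, Mat1 (0.17 ± 0.06), for a subunit of a cell cycle kinase, and Rrp1 (0.11 ± 0.07), for a DNA repair enzyme, do not belong to the group by their known products, nor do the transcription factor Myc and the translation helicase bel. All of the remaining 21 genes fell, also when adjusted over the list alone. Nnp-1 went from 61.2 ± 5.53 to 39.8 ± 1.46 CPM (-0.62 ± 0.06, adjusted p = 2.6e-05) and the nucleolar GTPase gene Ns2 from 59.3 ± 3.62 to 41.8 ± 2.71 CPM (-0.50 ± 0.06). Myc, a growth regulator in the list as fixed but not among these 21, changed by -0.89 ± 0.14 (adjusted p = 0.00064). The list was called (adjusted p = 3.2e-13, and 3.4e-14 without the 4 genes), but not with an estimated correlation (adjusted p = 0.27 and 0.22). In the list of cytosolic ribosomal proteins 4 of 90 genes fell and 0 rose, with 0 changes when adjusted over the list alone, and that list was not called (adjusted p = 0.86). The 4 were RpLP0-like (-0.39 ± 0.09) and RpL24-like (-0.27 ± 0.08), known by homology as ribosome assembly factors, and RpL10Ab (-0.16 ± 0.05) and RpL41 (-0.20 ± 0.06), so that 2 of 88 ribosomal protein genes fell. The RpL10Ab call was lost in 5 of the 11 fits that leave out 1 library.

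Of 12 genes of the mitochondrial genome 8 fell and 0 rose, also when adjusted over the list alone, with mt:CoIII at 8540 ± 852 and 6690 ± 434 CPM (-0.35 ± 0.08) and mt:ND4 at -0.78 ± 0.17. The share of all counts from mitochondrial genes was 8.37 ± 0.826% in w1118 and 6.66 ± 0.295% in the mutants (exact permutation test, p = 0.00433, 0.026 adjusted over 6 library measures). Of 72 genes for mitochondrial ribosomal proteins 21 fell and 0 rose (25 fell when adjusted over the list alone), among them mRpL54 (-0.56 ± 0.07) and mRpL39 (-0.31 ± 0.05). Of 61 nuclear oxidative phosphorylation genes 7 rose and 0 fell (4 rose when adjusted over the list alone), by small amounts such as 0.31 ± 0.06 for UQCR-Q and 0.17 ± 0.04 for ATPsynD. The 3 lists were called (adjusted p = 0.0043, 0.0016 and 0.025), none with an estimated correlation (adjusted p = 0.81, 0.87 and 0.87). The oxidative phosphorylation call was lost without mutant library 1 or 2 or w1118 library 2 (adjusted p up to 0.073).

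Neuron markers and Turandot and JAK/STAT genes were lower in part. Of 13 neuron markers 5 fell and 1 rose (10 and 1 when adjusted over the list alone), with the synaptic gene Snap25 at 5.10 ± 0.574 and 3.25 ± 0.284 CPM (-0.65 ± 0.10) and unc-13, on chromosome 4, up by 0.40 ± 0.08. Of 8 Turandot and JAK/STAT genes, components of the pathway included, 5 fell and 0 rose, also when adjusted over the list alone, among them vir-1 (-0.28 ± 0.06) and Socs36E (34.6 ± 13.6 to 15.7 ± 2.83 CPM, -1.14 ± 0.24). Both lists were called (adjusted p = 0.041 and 0.024), neither with an estimated correlation (adjusted p = 0.75 and 0.66). The neuron call was lost in 6 of the 11 fits that leave out 1 library, those without mutant library 2, 3 or 4 or w1118 library 2, 4 or 6 (adjusted p up to 0.091), without w1118 libraries 1 and 6 together (0.059), with the roX1 covariate (0.087) and with the replicate block (0.085, and 0.079 in the same 10 libraries without it). With the stricter filter neither list was called (adjusted p = 0.18 and 0.15).

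Cuticle genes went both ways, and some of the largest decreases rested on 2 control libraries. Of 76 genes of the cuticle list 27 fell and 11 rose (29 and 12 when adjusted over the list alone). One of the 76, Cpr (-0.01, not called), encodes the cytochrome P450 reductase and not a cuticle protein, and without it the list was called as before (adjusted p = 0.041). Cpr97Ea went from 15.2 ± 0.999 to 7.63 ± 0.871 CPM (-0.99 ± 0.08) and Cpr47Eb from 33.2 ± 6.18 to 72.6 ± 3.25 CPM (1.13 ± 0.11). The list was called (adjusted p = 0.041), but not with an estimated correlation (adjusted p = 0.87), nor with fry (0.076), the stricter filter (0.11), the roX1 covariate (0.17) or the replicate block (0.18, and 0.087 in the same 10 libraries without it), nor without mutant library 5 or w1118 library 3, 4 or 6 (adjusted p up to 0.098). The 6 largest decreases were TwdlH and Cpr65Ea, both cuticle genes, the peptidoglycan recognition gene PGRP-SB2 (13.7 ± 4.85 to 0.285 ± 0.190 CPM, -5.58 ± 0.48), CG32368, lectin-37Da and CG2150. TwdlH reached 395 CPM in w1118 library 1 and 118 CPM in w1118 library 6, against 2.90 to 6.69 CPM in the other w1118 libraries. Without libraries 1 and 6, an alternative added after seeing the data, TwdlH was at -1.24 ± 0.41 (adjusted p = 0.052, against -5.68 with all libraries), Cpr65Ea at -1.89 ± 0.39 (against -5.20), CG2150 at -2.42 ± 0.52 (against -4.74) and PGRP-SB2 at -5.69 ± 0.47. TwdlH was lost in 7 of the 11 fits that leave out 1 library, Cpr65Ea in 6 and CG2150 in 4, and lectin-37Da passed the filter in only 6 of them. Of the 27 lower cuticle genes 25 were also called lower without libraries 1 and 6, with a median log2 fold change of -1.02, against -1.09 with all libraries. In the chitin list 1 of 22 genes rose and 3 fell, with 1 change when adjusted over the list alone, among them the chitinase gene Cht5 (-1.69 ± 0.28), and the list was not called (adjusted p = 0.92).

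**Figure D2:**
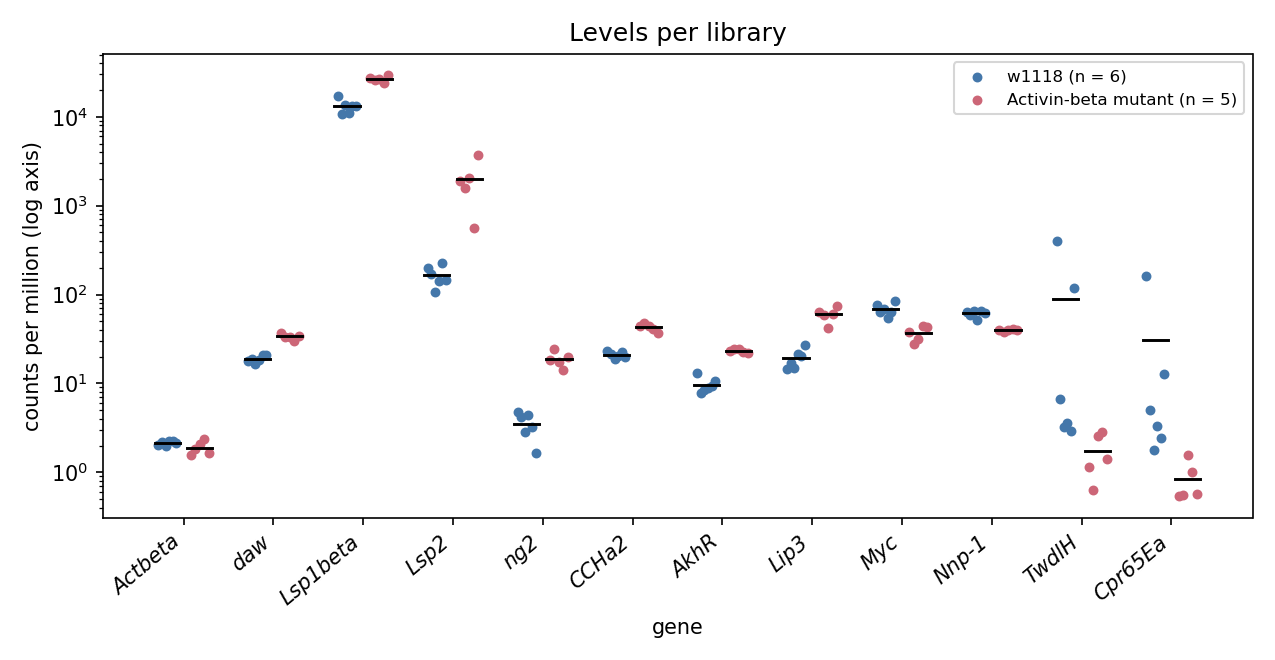
Points are CPM values of single libraries on a log axis, blue for w1118 (n = 6) and red for the Activin-β mutant (n = 5), and black bars are group means. Actbeta overlaps between genotypes, Lsp2 and CCHa2 are higher in all mutant libraries, and TwdlH and Cpr65Ea have single w1118 libraries at 395 and 160 CPM.

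Markers of most other tissues were not called as lists by camera. None of 24 muscle markers and none of 10 tracheal markers was called, with 0 also when adjusted over the list alone (list adjusted p = 0.86 and 0.92). Of 15 genes of the neuromuscular junction 2 fell and 0 rose, with 1 change when adjusted over the list alone, among them the calcium channel gene cac (-0.47 ± 0.12), and the list was not called (adjusted p = 0.14), except without w1118 library 2 (0.015). Fat body markers had 4 of 15 higher and 4 lower (9 changes when adjusted over the list alone, list adjusted p = 0.86). In midgut markers 5 of 16 were higher and 1 lower (8 changes when adjusted over the list alone, list adjusted p = 0.20, and 0.014 without w1118 library 2), with LManIV at 64.6 ± 20.2 and 511 ± 86.4 CPM (2.98 ± 0.20) and mex1 at -0.55 ± 0.08. Hemocyte markers had 3 of 13 higher and 2 lower (5 changes when adjusted over the list alone, list adjusted p = 0.86), the collagen genes vkg (-0.32 ± 0.05) and Col4a1 (-0.30 ± 0.05) being the lower ones. Malpighian tubule markers had 4 of 11 higher and 2 lower (8 changes when adjusted over the list alone, list adjusted p = 0.47), with the urate oxidase gene Uro up by 1.19 ± 0.14. Of 34 neuropeptide genes 2 rose and 5 fell (7 changes when adjusted over the list alone, list adjusted p = 0.86), and of 16 enteroendocrine genes 3 rose and 3 fell (6 when adjusted over the list alone, list adjusted p = 0.71), CCHa2 being in both lists.

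The remaining lists were not called by camera, and fry called 1 of them, insulin and TOR signaling. Glycolysis had 3 of 14 genes higher and 2 lower (7 changes when adjusted over the list alone, list adjusted p = 0.15, and 0.026 with the roX1 level as a covariate), with the fat body hexokinase gene Hex-C at -0.60 ± 0.10 and Pgi at 0.31 ± 0.08. The TCA cycle had 2 of 15 higher and 1 lower (2 when adjusted over the list alone, adjusted p = 0.71), including SdhB (0.26 ± 0.07) and kdn (-0.20 ± 0.05). Digestive carbohydrases had 2 of 14 higher and 3 lower (5 when adjusted over the list alone, adjusted p = 0.86), with the amylase gene Amy-d, 1 of a pair of near-identical copies, at -0.86 ± 0.11. Insulin and TOR signaling had 2 of 22 higher and 5 lower (8 when adjusted over the list alone, adjusted p = 0.42, and 0.033 towards lower with fry, 0.022 without dor, a vacuolar sorting gene), with the insulin-like peptide gene Ilp6 up by 1.03 ± 0.17 and S6k at -0.20 ± 0.04. The ecdysone response had 4 of 17 higher and 0 lower (5 when adjusted over the list alone, adjusted p = 0.92), among them br (0.36 ± 0.10) and usp (0.20 ± 0.06), whose call was lost in 6 of the 11 fits that leave out 1 library. Antimicrobial peptides had 1 of 17 higher and 1 lower (1 when adjusted over the list alone, adjusted p = 0.71), the latter Drsl5 (-1.35 ± 0.19). DNA replication and cell cycle had 2 of 24 higher and 0 lower (2 when adjusted over the list alone, adjusted p = 0.42), among them the mitotic phosphatase gene stg (0.46 ± 0.06). Amino acid catabolism had 4 of 19 higher and 6 lower (10 when adjusted over the list alone, adjusted p = 0.40), with Shmt at -0.42 ± 0.06 and Got2 at 0.33 ± 0.05. The median, the mean and the test differed in sign for the TGF-β, carbohydrase, insulin, ecdysone response, chitin, muscle, enteroendocrine, fat body, midgut, trachea and testis lists, none of which was called by camera.

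In all, camera called 17 of the 39 lists, 11 higher and 6 lower, and 3 of them with an estimated correlation. The fry test, which asks whether the genes of a list move on balance in 1 direction and does not compare them with other genes, called 18, among them insulin and TOR signaling and the sugar list, and not the cuticle list. The list test treats genes as nearly independent, and 19 of 100 regroupings of the same libraries, the real one included, called 17 or more lists. Of the 17 lists, 4 had a p as small in under 5 of the 100 regroupings: glue proteins, salivary gland markers, adipokinetic and nutrient hormones, and heat shock genes. The other 13 had it in 5 or more, among them storage proteins (5), lipid mobilization and β-oxidation (6) and ribosome biogenesis (7).

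The level of a male-specific RNA differed between libraries, and the sex of the pooled larvae is not given in the sources used here. The male-specific RNA gene lncRNA:roX1 stood at 128 ± 74.3 CPM in w1118 and 180 ± 58.4 CPM in the mutants (exact permutation test, p = 0.229), and lncRNA:roX2 at 2.41 ± 1.52 and 4.52 ± 1.94 CPM (p = 0.0823). In w1118 library 6 roX1 was at 18.2 CPM, against 86.7 to 219 CPM in the other w1118 libraries. None of 13 testis markers was called, with 0 also when adjusted over the list alone (list adjusted p = 0.71). With the roX1 level as a covariate, an alternative added after seeing the data, 2489 genes were called.

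Changed genes were spread over all chromosome arms. On 3L, 28.6% of 2078 tested genes were called, against 25.3% elsewhere (Fisher's exact test, odds ratio 1.19, 95% interval 1.06 to 1.32, adjusted p = 0.0057). On the X, 22.6% of 1710 were called, against 26.6% elsewhere (odds ratio 0.808, 0.713 to 0.915, adjusted p = 0.0039). Chromosome 4, which carries Actbeta, had 29 of 87 genes called (odds ratio 1.43, 0.883 to 2.28, adjusted p = 0.28). Genes are not independent replicates, so these intervals are too narrow to that extent.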

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

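The tests on developmental age and fat body share for the storage and glue genes, on shared lysozyme reads, on a mislabelled library and on dividing cells were chosen after the results they bear on were seen, as were the counts of regroupings per list. The reason given below for setting aside the age tests was also found only after their axis had been computed.

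Of 100 splits of the 11 libraries into 6 and 5, drawn with the real one among them, 1 called as many genes as the real split, the real one itself. It called 2740 genes and the highest of the others called 1483, in a split that sets 5 w1118 libraries against the 5 mutant libraries together with w1118 library 3. Chance can be excluded for the gene count. For the number of called lists it cannot: 19 of the 100 splits called at least the 17 lists of the real split, and the highest of the others called 20.

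In 14 of 180 sets of values, a library stood far from the rest of its group, where chance gives about 1 in 20. In w1118 library 1, TwdlH was at 395 CPM (2.90 to 118 in the others), Cpr65Ea at 160 CPM (1.77 to 12.6), CG2150 at 38.9 CPM (0.705 to 8.63) and cac at 4.49 CPM (6.20 to 7.17). In w1118 library 2, CG32368 was at 14.9 CPM (0.8 to 3.71), lectin-37Da at 24.5 CPM (0.278 to 3.14), ATPsynD at 418 CPM (441 to 449) and Acox57D-p at 155 CPM (125 to 128). In w1118 library 4, LysC was at 0.216 CPM and Socs36E at 60.9 CPM (21.8 to 34.8), and in w1118 library 5, GstZ1 was at 13.2 CPM (14.3 to 14.9). Among the mutants, Ilp6 was at 8.39 CPM in library 3 (4.62 to 5.41), cac at 5.42 CPM in library 5 (4.16 to 4.46) and GstZ1 at 30.2 CPM in library 2 (27.5 to 28).

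The lists of storage proteins, glue proteins (4 of 12 genes tested) and salivary gland markers were higher in the mutants. A single deviating library is excluded. The 3 lists had a camera adjusted p of at most 0.00013 in all 11 fits that leave out 1 library. A larger share of fat body is not decided. The 13 fat body markers outside the storage list had a median log2 fold change of -0.129 (bootstrap interval over genes -0.303 to 0.0592), where at least 0.5 was required. They moved both ways, as with Ilp6 (1.03) and Adgf-D (-0.71), and Col4a1 is also a hemocyte marker. Their median argues against a rise shared by these markers, but it cannot measure the share of fat body. A difference in developmental age cannot be told apart from the genotype, which may itself change the pace of development, because each genotype was sampled at 1 time. The fold changes followed the main axis among the w1118 libraries with a Spearman rho of 0.11 across genes (genes are not independent replicates), and the storage and glue genes had a median loading of -0.0025, on the other side of that axis, which by the bound set for the test would argue against age. That value is close to 0, and the axis is not specific to age: it ranks the 6 w1118 libraries in the same order as roX1, from 18.2 to 219 CPM, while libraries 1 and 6 at its low end also have the highest TwdlH, at 395 and 118 CPM, so the test decides nothing.

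A group of 12 genes had a mean of 2 CPM or more in 1 genotype and under 0.3 CPM in the other. Among them were w, LysC and the salivary gland marker PH4alphaSG2. A mean need not hold in each library: lectin-37Da was at 24.5 CPM in w1118 library 2 and 0.278 to 3.14 CPM in the other w1118 libraries. A mislabelled library would show in w, where 0 libraries lay within the range of the other group, but w helps to define these genes, so that count decides nothing; on the first principal component of all tested genes the mutants lay at 19.3 to 40.1 and w1118 at -54.2 to -5.77, which argues against a swap between the groups and leaves a sample from outside open. Reads shared between near-identical lysozyme genes stay open for LysC and LysD: the summed level of the 6 tested Lys genes was 4.27 times as high in the mutants, but the sum need not be conserved if reads that match several copies were dropped, and their handling is not given in the sources used here. A different genetic background of the strains stays open for the genes other than w. Of the 12 genes 16.7% lay within 100 kb of another of them. These were CG34278, listed in the mutants, and TwdlW, listed in w1118 at 4.16 ± 7.93 CPM. The share thus rests on 1 gene with a wide spread between the w1118 libraries. Random draws from the changed genes had a median of 0% and a 95th percentile of 16.7%, which the share of the 12 did not exceed. For w a strain difference is shown, since its mutant allele names the control strain, with 2 counts in w1118 and 1352 in the mutants. For the other genes background and Actbeta genotype cannot be told apart with 1 control strain.

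Ribosome biogenesis transcripts were lower in the mutants. The choice among 5 scalings is excluded, since the median log2 fold change of the list was at most -0.431 over them. The median over all tested genes moved only from -0.0188 to 0.0171 between them, so a shift shared by all 5 was not tested. The DNA replication and cell cycle list did not fall, with a median of 0.0712 (bootstrap interval over genes -0.0345 to 0.112), where -0.2 or lower was required. This argues against a fall shared by those genes. The list does not count dividing cells, so a smaller share of them is not excluded. A difference in developmental age cannot be told apart from the genotype: the list lay at percentile 5.73 of random lists on the same w1118 axis, inside the range set for no decision, and that axis has the limit given above. An effect of Actbeta itself on this group is a hypothesis that the design leaves beside age, strain background and a smaller share of dividing cells.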

How the results depend on the processing

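Upper-quartile scaling, leaving out w1118 libraries 1 and 6, the roX1 covariate, the fit to 10 libraries without the block and the lists without 13 members that encode other products were chosen after seeing the data. The number of changed genes was 2498 to 3011 over the other planned settings of scaling, filter, estimation and test, and 2186 to 2725 over the fits that leave out 1 library (1016 to 1334 higher, 1166 to 1467 lower). The 3011 came from DESeq2, which in the simulated counts called more unchanged genes (13.3% of its calls) than edgeR (4.44%). Tested against a fold of 1.5, it was 261, with 169 higher and 92 lower, since that test asks for a larger change. The number of called lists was 14 to 17 over the fits that leave out 1 library and 3 with an estimated correlation, which allows for genes that vary together. Without the 13 members it was 17 and no list changed its call. Leaving out w1118 library 2 gained the midgut and neuromuscular junction lists. The stricter filter ended 4 list calls, the block 3 (2 in the same libraries without it), the roX1 covariate 2 with 1 gained, leaving out w1118 libraries 1 and 6 ended 2, leaving out the 20 most abundant genes 1, and fry 1 with 2 gained. Without w1118 libraries 1 and 6, 2331 genes were called, and 2120 of them were among the 2740. Actbeta was not called in any fit, at -0.27 to -0.11 over those that leave out 1 library. Replicate numbers did not pair the samples: the correlation of same-numbered libraries was -0.233 to 0.299, and only number 2 correlated best with its own. With the replicate block over 10 libraries 2296 genes were called, against 2491 in the same libraries without it. No called list or called named gene reversed its direction under any alternative, but the balance of higher and lower genes turned under some, as given above. Of 86 named genes besides Actbeta, DESeq2 gave a value for 85 and ended the call of 1, limma-voom ended 4, no filter 4, the replicate block 9 (5 in the same libraries without it), the roX1 covariate 6, leaving out w1118 libraries 1 and 6 ended 5, and the fold of 1.5 ended 48. Counts under the floor limit only the genes listed in 1 genotype.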

Other observations

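All of the gene families below were chosen after the single genes were seen, by symbol prefix, and 28 families were tested together with camera. Lysozyme genes were the family with the smallest adjusted p: 5 of 6 rose and 1 fell (adjusted p = 7.3e-63, and 7.2e-06 with an estimated correlation). LysS rose from 172 ± 23.4 to 689 ± 58.1 CPM (2.00 ± 0.09), LysB from 125 ± 22.3 to 241 ± 12.4 CPM and LysE from 27.5 ± 4.16 to 60.5 ± 3.21 CPM, while LysX changed from 0.997 ± 0.627 to 0.0705 ± 0.0320 CPM. Several are near-identical neighbours on 3L, so single values are uncertain. Of 11 alkaline phosphatase genes 9 rose and 0 fell (adjusted p = 8.7e-13, and 0.012 with an estimated correlation), with Alp4 up by 1.30 ± 0.13. Of 4 genes for thioester-containing immune proteins 3 rose (adjusted p = 0.00023, and 0.023 with an estimated correlation), with Tep4 at 42.5 ± 7.38 and 235 ± 39.6 CPM (2.47 ± 0.13).

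Of 23 genes of the vacuolar proton pump, which acidifies lysosomes and the gut lumen, 16 rose and 0 fell (adjusted p = 5.4e-06, but 0.38 with an estimated correlation), with a median log2 fold change of 0.34. Of 6 lysosomal α-mannosidase genes 5 rose and 0 fell (adjusted p = 7.2e-06, but 0.32 with an estimated correlation). C-type lectin genes had 2 of 8 higher and 1 lower (adjusted p = 0.02, but 0.11 with an estimated correlation). Tweedle cuticle genes had 6 of 21 lower and 0 higher and were not called (adjusted p = 0.068). Their median log2 fold change was -2.90 over 21 genes with all libraries and -0.29 over 20 genes without w1118 libraries 1 and 6, an alternative added after seeing the data.

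Hr4 and ftz-f1, genes of the ecdysone cascade, were at 7.57 and 40.3 CPM in w1118 library 1, against 0.249 to 2.82 and 12.5 to 18.9 CPM in the other w1118 libraries. The testis gene betaTub85D was at 0.0784 CPM in w1118 library 6, against 0.297 to 1.58 CPM in the others.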
